A study of Poecilia mexicana with 31 samples.

How the data were processed

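Methylated DNA immunoprecipitation sequencing (MeDIP-seq) was done on red blood cells of 31 individual Poecilia mexicana, a livebearing fish. Per the labels, DNA was sonicated, made single-stranded, and pulled down with an antibody against methylated cytidine before library preparation. The fish fell into 8 groups by the water of their origin (sulfidic or non-sulfidic spring), their rearing (caught in the wild, or bred in the laboratory in non-sulfidic water) and their sex. Each group held 4 fish, except the non-sulfidic wild males with 3. The labels give no date or batch of immunoprecipitation or sequencing, so none could enter a test.

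The authors deposited 4 tables, each setting the sulfidic against the non-sulfidic fish of 1 sex and 1 rearing place, and no library was in more than 1 table. The submitters' processing notes name FastQC, Trimmomatic, Bowtie2, SAMtools and edgeR. The genome build, the versions of these tools and the read filters are not given in the sources used here, and scaffold names are printed as the tables have them. Per the file headers, each table holds a deposited read count per library for each of 8026218 windows of 100 bases on 18105 scaffolds. These counts were whole numbers with no normalization, and the highest was 300 in each of the 31 libraries, reached at 3 to 48 windows, a ceiling whose origin is not given in the sources used here. The deposited RPKM values (reads scaled to window length and read total) were used in 1 library only, and gave a total of 25036819 reads, each counted in 1.499 windows. The deposited log2 fold change of the authors compares sulfidic with non-sulfidic fish: over windows it correlated with the log2 ratio of the group means at 0.999 or above in each table. The deposited p-value and adjusted p-value come from the authors' edgeR test, and were present only where the counts of a table summed to at least 10.

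Window counts of a library summed to between 26208975 and 42045269. Reads amplified by PCR are not independent molecules, so a limit taken from a count of 0 covers counting error only; it was set at 3 counts over the group. Neighbouring windows share reads and fragments, so called windows were also merged into regions.

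Counts were tested with edgeR 4.0.16 in R 4.3.3 (quasi-likelihood fit and F test, two-sided, with normalization by trimmed mean of M values, TMM). Windows with a mean count of at least 5 per library were tested, and p-values were adjusted by the Benjamini-Hochberg method and called at an adjusted p of 0.05. Each of the 4 comparisons had its own fit with its own libraries. A further fit of all 31 libraries, with a mean for each of the 8 groups, gave 5 contrasts: the origin effect averaged over the comparisons, its difference between wild and lab fish, its difference between males and females, the wild minus lab difference and the male minus female difference. Levels are printed as counts scaled to the library's total over the 1956264 windows tested in all fish, times its TMM factor (CPM); log2 CPM adds a prior count of 2. The tests by sign used the windows tested, and the factors, of the comparison measured. Differences printed with a standard error (SE) are differences of mean log2 CPM between groups, and fold changes of called windows are those of edgeR. Called windows of the same direction were merged into a region where the gap between them was at most 1000 bases, and overlaps of regions were counted with bedtools 2.31.1.

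Whether a difference found in some fish was present in others was tested by sign. Windows called in wild fish were measured in lab fish of the same sex, and windows called in males were measured in females of the same rearing. The share of windows with the same sign was compared with that under every split of the 8 measured fish into 4 and 4, in an exact permutation test of 70 splits, one-sided for a higher share. The smallest p this design allows is 0.0143. For the interaction of origin and rearing, residuals of a fit without it were exchanged between fish of the same rearing and sex. Each count was moved to the same quantile of a negative binomial distribution around the fitted mean of the fish that received it. Principal components of log2 CPM were computed over the windows tested in all fish. The share of variance of the first 3 components between the levels of origin, rearing and sex was tested with 100000 permutations, and p-values were adjusted over these 9 tests. Python 3.11.15 with numpy 2.4.6, pandas 2.3.3, scipy 1.17.1 and matplotlib 3.10.9 was used.

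Regions and windows were named by rule: in each of the 4 comparisons, the 3 regions of each direction with the most called windows, and, among windows called in all 4 comparisons in the same direction, the 5 of each direction with the smallest p for the origin effect in all fish. The tests of the comparisons and the rule for named items were chosen before the data were examined, as were alternatives that covered the normalization, the count minimum, DESeq2 1.42.0 in place of edgeR, the threshold, 1000-base bins, the gap between windows of a region, and leaving out each fish in turn. For fits of all fish, leaving out fish, exchanging labels and DESeq2 were run on every 20th window. Removing each library's trend against window level, leaving out windows with a count above 150, leaving out libraries that lay apart, and all alternative settings for named regions and windows were added after seeing the data. No genome sequence or annotation was used here, so tests of genes and of gene lists were not run, and no region is assigned to a gene.

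The fits were tested on simulated data: counts were drawn for 20000 windows at the measured levels and depths with a fixed spread, and 100 windows were changed 2-fold and 100 windows 4-fold. In the single comparisons 24% to 32% of the 2-fold changes and 86% to 94% of the 4-fold changes were recovered. In the fit of all fish, the origin effect recovered 94% and 100%, and the interactions recovered at most 27% of the 2-fold changes and at least 94% of the 4-fold changes. Between 1.6% and 8% of calls were false. The spread was the same at every window, so these shares need not hold where fish differ more.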

Results

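Methylated DNA immunoprecipitation sequencing was used to measure where methylated fragments were recovered in red blood cells of 31 individual Poecilia mexicana, a livebearing fish. The fish descended from a spring rich in hydrogen sulfide (sulfidic origin) or from a nearby spring without it (non-sulfidic origin), and were caught in the wild or bred in the laboratory in non-sulfidic water. Each of the 8 groups of origin, rearing and sex held 4 fish, except the non-sulfidic wild males with 3. Window counts of a library summed to between 26208975 and 42045269, and group means ran from 29595611 ± 3373823 (SD, n = 4) in sulfidic wild females to 38391867 ± 3283624 (SD, n = 4) in sulfidic lab females. The signal of a window or region is a normalised read count and not a percentage of methylated cytosines. It can also differ between groups where the sequence itself or its copy number differs, and no input libraries were used here.

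Wild and lab fish were the most separate groups of libraries. Of the variance in signal over 1956264 windows, component 1 held 30%, and 81.4% of that component lay between wild and lab fish (permutation p = 1e-05, the smallest that the permutations can give; adjusted p = 4.5e-05; n = 15 wild and 16 lab fish). The wild libraries scored from 319.7 to 453.2 on this component. Most lab libraries scored from -695.0 to -244.9, while non-sulfidic lab male 4 scored 301.4, sulfidic lab female 1 scored -30.0 and non-sulfidic lab female 2 scored -47.0. Origin accounted for 35.9% of component 2 (adjusted p = 0.00087) and 56.2% of component 3 (adjusted p = 4.5e-05), which held 6.1% and 4.8% of the variance. Over the 10% of windows with the highest variance, component 2 carried 95.3% of its variance between origins and component 3 only 0.1% (adjusted p = 0.989). Sex accounted for at most 0.1% of each of the 3 components, with adjusted p = 0.983 in each permutation test.

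**Figure D1:**
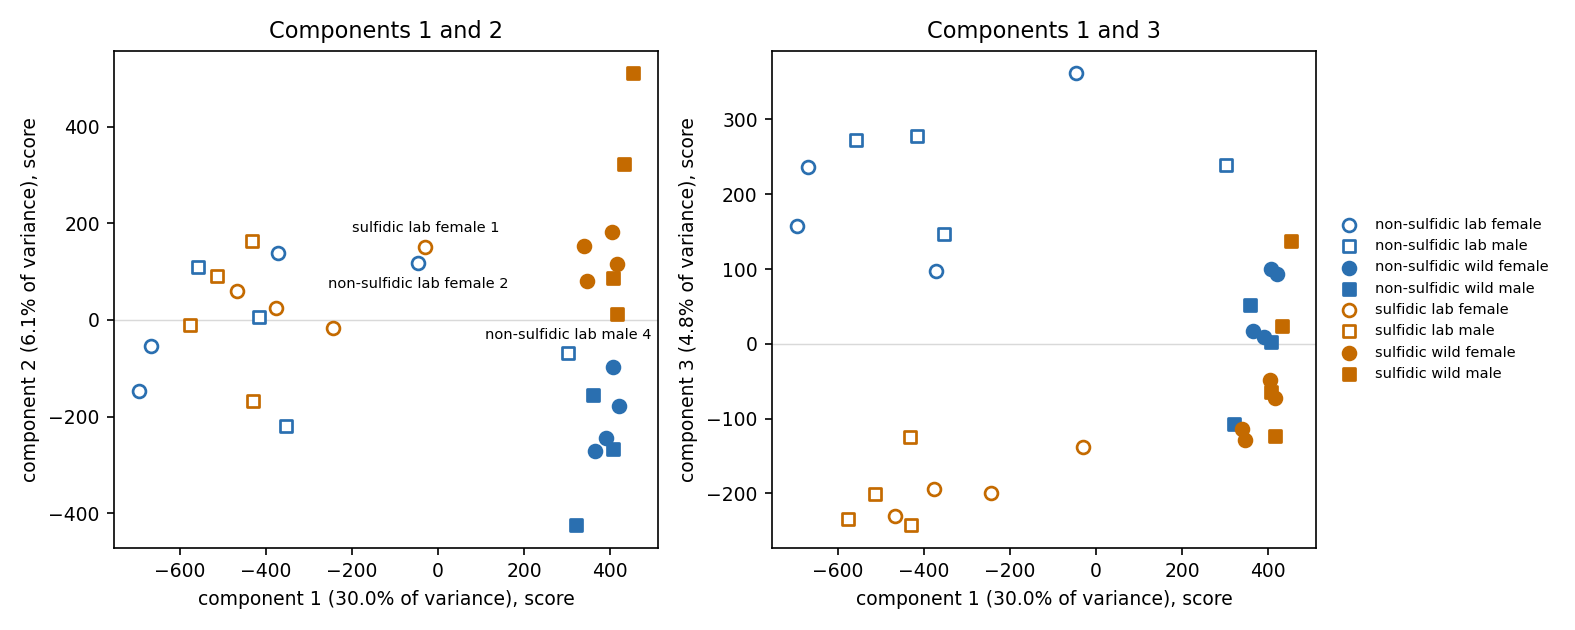
Scores of the 31 libraries on component 1 (x axis) against component 2 (left) and component 3 (right), in units of the component score; orange marks sulfidic and blue non-sulfidic origin, filled symbols wild and open symbols lab fish, squares males and circles females. Wild libraries lie between 319.7 and 453.2 on component 1, and 3 named lab libraries lie between them and the other lab libraries.

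The first comparison asked where wild males of the sulfidic spring differ from wild males of the non-sulfidic spring. In the 4 sulfidic fish 10224 windows had a higher and 5111 windows a lower signal than in the 3 non-sulfidic fish, of 2048225 tested, with median log2 differences of 1.29 and -1.94. The called windows formed 5564 higher and 2796 lower regions. The higher region with the most called windows lay on NW_015096928.1 from base 58101 to 64900, where sulfidic males had 137 ± 6.55 CPM (SD, n = 4) and non-sulfidic males 54.7 ± 8.03 CPM (SD, n = 3), a log2 difference of 1.33 ± 0.13 (SE). Those next in number lay on NW_015096486.1 from 93001 to 97200 (log2 difference 1.21 ± 0.21, SE) and on NW_015097917.1 from 20301 to 26600 (2.72 ± 0.98, SE). The lower regions lay on NW_015095229.1 from 183401 to 189400 (-1.16 ± 0.13, SE), on NW_015097072.1 from 32801 to 38000 (-1.18 ± 0.14, SE) and on NW_015098779.1 from 22101 to 24900 (-2.96 ± 0.96, SE), where the ranges of the groups overlapped. On NW_015097917.1 the difference was 3.63 and 2.03 without non-sulfidic wild males 2 and 3, and on NW_015098779.1 it was -3.68 and -2.33 without non-sulfidic wild males 1 and 2. On NW_015095229.1 the level was 39.1 ± 5.75 CPM (SD, n = 4) in sulfidic and 87.2 ± 8.63 CPM (SD, n = 3) in non-sulfidic males. The test was edgeR at an adjusted p of 0.05, and the smallest adjusted p of a window in these 6 regions ran from 8e-08 to 4.8e-05. The balance of directions moved with the scaling: 66.7% of the windows were higher with TMM. With relative log expression (RLE) size factors in place of TMM 8542 were higher and 5307 lower, and with library totals alone 7521 and 6871. With each library's trend against window level removed, a test chosen after seeing the data, 4912 were higher and 6467 lower. With a mean count of at least 10, 3752 were higher and 3732 lower. On every 20th window DESeq2 called 265 windows and edgeR 791, but DESeq2 gave no adjusted p for 96957 of 102061. The count rose to 25886 without sulfidic wild male 4, and fell to 6495 without non-sulfidic wild male 1, to 7083 without non-sulfidic wild male 2, to 7762 without sulfidic wild male 1 and to 8913 without sulfidic wild male 3.

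**Figure D2:**
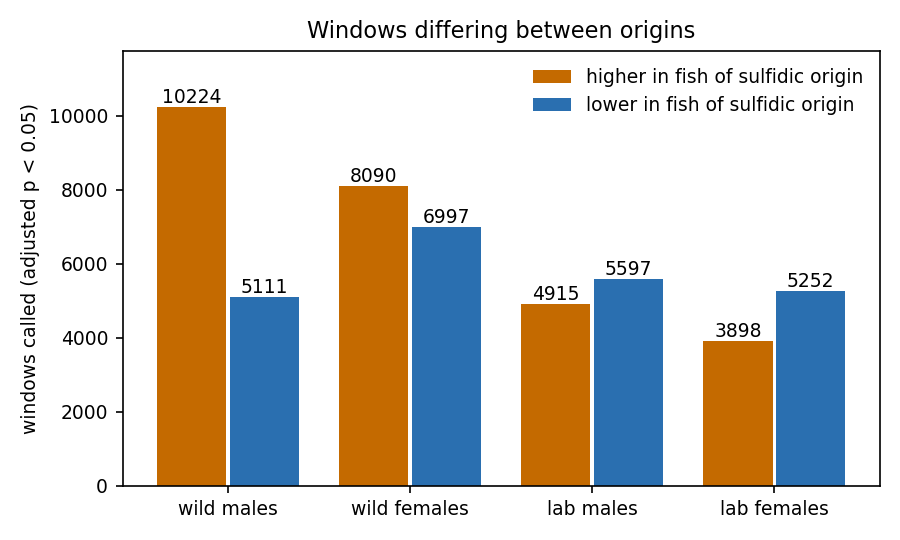
Number of windows called at an adjusted p of 0.05 (y axis, from 0) in each of the 4 comparisons (x axis), higher in fish of sulfidic origin in orange and lower in blue. Wild males had 10224 higher and 5111 lower windows, and lab females 3898 higher and 5252 lower windows.

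In wild females the same question gave 8090 higher and 6997 lower windows in the 4 sulfidic fish than in the 4 non-sulfidic fish, of 1932451 tested, with median log2 differences of 1.11 and -1.84. They formed 4401 higher and 3492 lower regions. The region with the most called windows was lower in sulfidic fish and lay on NW_015097488.1 from 34301 to 40800, with 3.45 ± 2.47 CPM in sulfidic and 97.3 ± 19.5 CPM in non-sulfidic females (SD, n = 4 each; log2 difference -5.12 ± 0.63, SE). The other lower regions lay on NW_015098779.1 from 22001 to 26300 (-1.93 ± 0.53, SE) and on NW_015096559.1 from 91701 to 98800 (-1.06 ± 0.80, SE), where non-sulfidic wild female 2 had 190 CPM, the other 3 non-sulfidic wild females 17.4 to 31.1 CPM and sulfidic females 18.1 ± 1.63 CPM (SD, n = 4). On NW_015096559.1 the ranges of the groups overlapped, and without that fish the difference was -0.28. On NW_015098112.1 it was 3.12 without non-sulfidic wild female 3, and on NW_015097420.1 it was 3.35 and 1.14 without non-sulfidic wild females 1 and 3. The higher regions lay on NW_015098112.1 from 25801 to 30100 (2.48 ± 0.78, SE), on NW_015097842.1 from 18901 to 23200 (1.78 ± 0.22, SE) and on NW_015097420.1 from 23601 to 27900 (2.66 ± 1.55, SE). On NW_015097842.1 sulfidic females had 36.3 ± 5.54 CPM and non-sulfidic females 10.7 ± 3.00 CPM (SD, n = 4 each). The edgeR test gave a smallest adjusted p between 3e-24 and 0.00016 in these 6 regions. With TMM 53.6% of the called windows were higher, against 6560 higher and 7957 lower with library totals alone, and 5058 and 7453 with the trend against window level removed. With a mean count of at least 10, 4010 were higher and 4783 lower. On every 20th window DESeq2 called 170 windows (78 higher and 92 lower), and edgeR 835.

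In lab males, bred in non-sulfidic water whatever their origin, 4915 windows were higher and 5597 lower in the 4 fish of sulfidic origin than in the 4 of non-sulfidic origin, of 1948416 tested, with median log2 differences of 1.95 and -1.97. They formed 3031 higher and 3164 lower regions. The lower region with the most called windows lay on NW_015098493.1 from 12001 to 16500, with 0.651 ± 0.293 CPM in sulfidic and 33.1 ± 13 CPM in non-sulfidic males (SD, n = 4 each; log2 difference -5.50 ± 0.40, SE). The other lower regions lay on NW_015096896.1 from 86401 to 91100 (-1.97 ± 0.32, SE), with 12.6 ± 5.40 CPM in sulfidic and 46.4 ± 3.02 CPM in non-sulfidic males (SD, n = 4 each), and on NW_015098779.1 from 22101 to 26300 (-1.86 ± 0.33, SE). The higher regions lay on NW_015094562.1 from 155601 to 161500 (1.73 ± 0.39, SE), on NW_015097420.1 from 23601 to 27900 (2.97 ± 1.65, SE) and on NW_015097917.1 from 25601 to 30500 (1.91 ± 2.12, SE), a difference within the spread between fish. On NW_015097917.1 it was 0.78 and 3.57 without sulfidic lab males 3 and 4, and 1.17 and 2.62 without non-sulfidic lab males 1 and 2. On NW_015097420.1 it was 1.33, 3.56 and 3.64 without non-sulfidic lab males 2, 3 and 4. The edgeR test gave a smallest adjusted p between 6.2e-09 and 0.0026 in these 6 regions. With a mean count of at least 10, 2929 were higher and 3087 lower, and on every 20th window DESeq2 called 235 windows and edgeR 514. The count fell to 5642 without sulfidic lab male 4 and to 5914 without sulfidic lab male 1.

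In lab females 3898 windows were higher and 5252 lower in the 4 fish of sulfidic origin than in the 4 of non-sulfidic origin, of 1934167 tested, with median log2 differences of 1.76 and -1.63. They formed 1939 higher and 3031 lower regions. The region with the most called windows was higher in sulfidic fish and lay on NW_015099078.1 from 2701 to 10000, with 51.6 ± 29.1 CPM in sulfidic and 5.77 ± 2.26 CPM in non-sulfidic females (SD, n = 4 each; log2 difference 3.04 ± 0.55, SE). The other higher regions lay on NW_015097309.1 from 35001 to 41500 (3.39 ± 0.65, SE) and on NW_015094562.1 from 156001 to 161500 (1.94 ± 0.40, SE). The lower regions lay on NW_015095229.1 from 183701 to 189500 (-1.43 ± 0.31, SE), on NW_015097072.1 from 32801 to 38000 (-1.38 ± 0.26, SE) and on NW_015098779.1 from 22501 to 26300 (-1.60 ± 0.30, SE). The smallest adjusted p in the edgeR test ran from 3e-08 to 0.00028 in these 6 regions. The balance of directions turned in some settings of the scaling and the count minimum. With library totals alone 4665 windows were higher and 4537 lower, and with the trend against window level removed 4706 and 4439. With a mean count of at least 10 there were 3220 and 2791. RLE size factors moved the median log2 difference of the tested windows by 0.0 from that with TMM. In 1000-base bins 2822 were higher and 6333 lower, and on every 20th window without a count minimum 162 and 549. On that subset DESeq2 called 178 windows and edgeR 434, but DESeq2 gave no adjusted p for 20539 of 96294. The count fell to 5157 without sulfidic lab female 4 and to 6076 without non-sulfidic lab female 1. Position between the origins, measured at windows called in the other 3 comparisons, placed non-sulfidic lab female 3 at 0.467, between the other non-sulfidic lab females (0.007 to 0.073) and the sulfidic lab females (0.932 to 1.02).

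**Figure D3:**
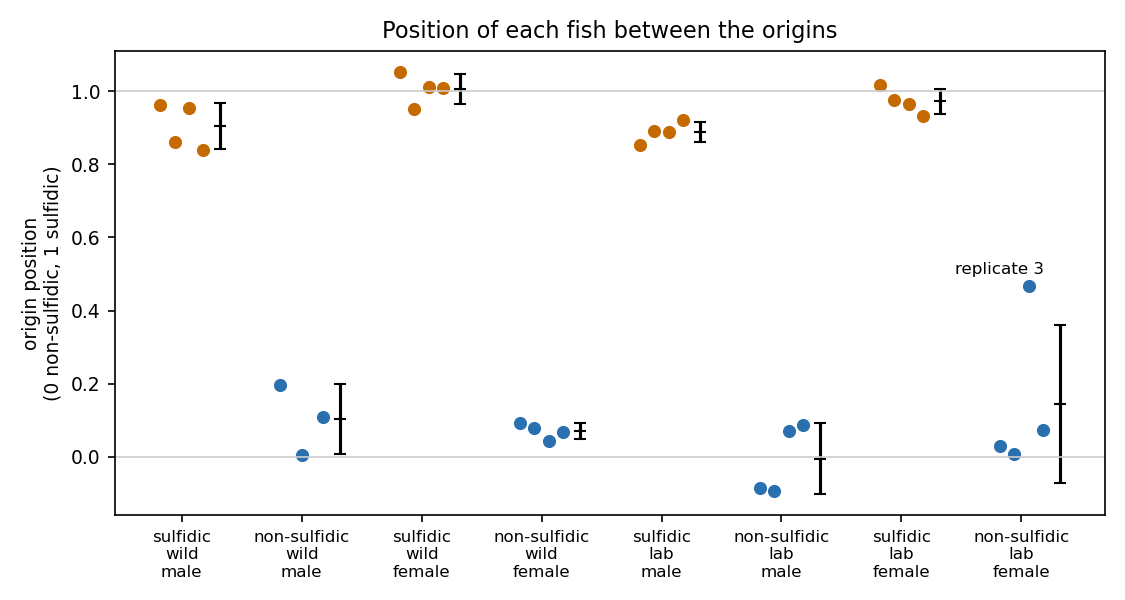
Position of each fish between the origins (y axis, a ratio without unit, 0 for the mean non-sulfidic and 1 for the mean sulfidic fish of the other sex and the same rearing) in the 8 groups (x axis); points are fish, bars the mean and SD. Sulfidic fish lie between 0.838 and 1.05, and non-sulfidic fish between -0.092 and 0.197 except lab female 3 at 0.467.

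Of 38083 windows called in at least 1 comparison, 29365 were called in 1 comparison only. Differences between the origins were shared across sex and rearing at 788 windows, 275 higher and 513 lower in sulfidic fish in all 4 comparisons, in 414 regions on 348 scaffolds. At the lower windows the median log2 difference ran from -2.70 in lab females to -2.36 in wild males, and at the higher windows from 1.68 in wild males to 2.09 in lab males. The region on NW_015095229.1 from 183401 to 189400 had called windows in all 4 comparisons, with log2 differences of -1.16 ± 0.13 in wild males, -0.87 ± 0.22 in wild females, -1.03 ± 0.21 in lab males and -1.38 ± 0.31 in lab females (SE). The region on NW_015099078.1 was higher in sulfidic fish in all 4 comparisons, with log2 differences from 1.87 ± 0.47 in lab males to 5.27 ± 1.80 in wild females (SE). The window on NW_015099381.1 from base 8901 had 0 counts in sulfidic wild males, lab males and lab females and 1 count over the 4 sulfidic wild females, against 1.03 ± 0.166 CPM (SD, n = 3) to 1.83 ± 0.433 CPM (SD, n = 4) in non-sulfidic groups. Against 3 counts over the group, that was at least 37.9-fold lower in wild males, 67.2-fold in lab males and 65.2-fold in lab females, and in wild females the ratio was 112-fold (95% counting interval 19.7 to 4440). The window on NW_015095294.1 from 185001 was lower by log2 differences of -4.45 ± 0.32 to -3.72 ± 0.63, and that on NW_015094692.1 from 196101 by -3.83 ± 0.32 to -2.75 ± 0.28 (SE). The sulfidic groups had 5 to 10 counts at the former and 1 to 5 at the latter, so the prior count makes these differences smaller. As ratios of counts summed over the fish and scaled to their totals, the former was 26.8-fold to 55.3-fold lower. The latter was 115-fold lower in wild males (95% counting interval 20.2 to 4610), 20.6-fold in wild females (6.76 to 102), 35.1-fold in lab males (14.7 to 109) and 38.5-fold in lab females (14.7 to 143). Windows on NW_015096230.1 from 120801 and on NW_015095051.1 from 295501 were lower by -2.83 ± 0.39 to -2.26 ± 0.30 and by -2.37 ± 0.14 to -1.84 ± 0.37 (SE). Adjacent windows on NW_015095180.1 from 224501 and 224601 were higher by log2 differences of 1.61 ± 0.68 to 2.59 ± 0.22 and of 1.47 ± 0.61 to 2.07 ± 0.23 (SE). The lowest of these were in wild males, whose groups overlapped at 224601, and were 2.28 and 2.06 without non-sulfidic wild male 2. The window on NW_015098560.1 from 30801 was higher by 4.25 ± 0.25 in wild males and 4.56 ± 0.37 in wild females, but by 2.39 ± 0.64 in lab males (3.01 without non-sulfidic lab male 4) and 1.97 ± 0.61 in lab females (SE). Adjacent windows on NW_015097309.1 from 56101 and 56201 were higher as well, the latter at least 13.9-fold in wild males against 3 counts over the group, since the 3 non-sulfidic wild males had 0 counts. In the fit of all 31 fish the adjusted p for the origin effect at these 10 windows was at most 1.5e-18 (edgeR).

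**Figure D4:**
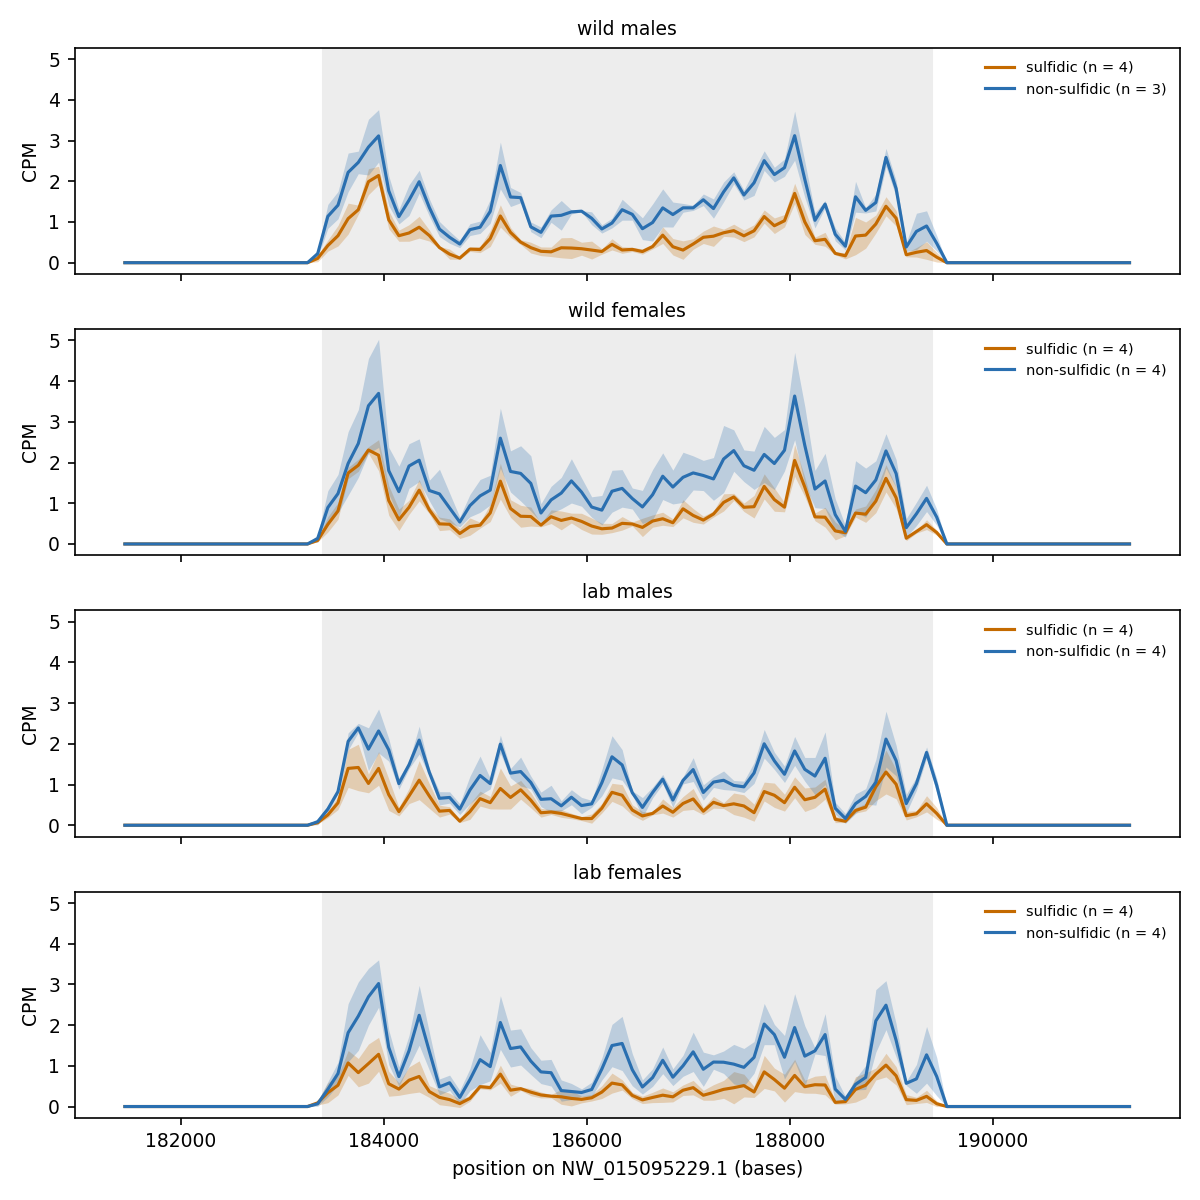
Signal along NW_015095229.1 (x axis, position in bases) in CPM per 100-base window (y axis) for the 4 comparisons, orange for sulfidic and blue for non-sulfidic origin; lines are group means, bands 1 SD, and grey marks the region from 183401 to 189400. The sulfidic mean lies below the non-sulfidic mean over the region, with log2 differences of the summed signal from -1.38 in lab females to -0.87 in wild females.

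Called windows were shared between all pairs of comparisons. Wild males and wild females had 4500 windows called in the same direction, 32.1% of the smaller list, and 1 in opposite directions. Lab males and lab females shared 3152 windows, 36.8% of the smaller list, and 5 had opposite directions. Between wild and lab fish the share was 21.5% in males (1812 windows, 49 opposite) and 29.0% in females (2290 windows, 31 opposite). Wild females and lab males, which differ in sex and rearing, shared 30.8% (2567 windows, 21 opposite), and wild males and lab females 20.2% (1591 windows, 54 opposite). By chance 11.8 to 22.5 windows per direction were expected in the males and 15.5 to 16.7 in the females. As regions that overlap by at least 1 base, 28% of the smaller list was shared between the sexes in the wild and 34.1% in the laboratory, and 15.6% between wild and lab males.

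The next comparison asked whether differences of wild fish were also present in fish bred in non-sulfidic water. Of the 15087 windows called in wild females, 74.0% had the same sign in lab females, with a median log2 difference of 0.43 in the direction of the wild fish (exact permutation p = 0.0429, one-sided, 70 splits of 4 against 4 fish; adjusted p = 0.0572 over the 4 sign tests). Of the 15335 windows called in wild males, 66.2% had the same sign in lab males, with a median of 0.22 (exact permutation p = 0.114, one-sided, 70 splits; adjusted p = 0.114). In males the share was 81.9% at windows lower in wild sulfidic fish and 58.4% at windows higher in them. Among the 5546 windows of wild males at an adjusted p of 0.01 the share was 79.4% (exact p = 0.0286). With the trend against window level removed it was 77.5% (exact p = 0.0286). In females the share was 82.2% at an adjusted p of 0.01 (exact p = 0.0286), 81.1% with the trend removed (exact p = 0.0143) and 68.6% with 1 window per region (exact p = 0.0714), and in males 62.9% with 1 window per region (exact p = 0.243). Without each lab female in turn the share in females stayed between 71.6% and 75.6%, with an exact p from 0.0286 to 0.114 over 35 splits. The p was 0.0857 without sulfidic lab female 1 or 2 or non-sulfidic lab female 2 or 4, 0.0571 without sulfidic lab female 3 or 4, 0.114 without non-sulfidic lab female 1 and 0.0286 without non-sulfidic lab female 3.

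Differences found in males were present in females of the same rearing place. Of the windows called in wild males 94.3% had the same sign in wild females, and of those called in lab males 94.3% had the same sign in lab females (exact permutation p = 0.0143 in each, one-sided, the smallest that 70 splits of 4 against 4 fish allow; adjusted p = 0.0286). The median log2 difference in the direction of the males was 0.64 in wild and 0.98 in lab females. The highest share under another split was 88.8% in wild and 92.0% in lab females.

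In the fit of all fish 25640 windows were higher and 27283 lower in sulfidic fish on average over the 4 comparisons, of 1956264 tested. Their median log2 differences were 0.76 and -0.86, and they lay on 5739 scaffolds (edgeR, adjusted p of 0.05, n = 16 sulfidic and 15 non-sulfidic fish). Among scaffolds with at least 200 tested windows, the share of called windows was highest on NW_015096559.1 (31.8% of 349 windows, 104 of them lower and 7 higher), on NW_015097488.1 (25.6%) and on NW_015096928.1 (25.2%, with 55 higher and 0 lower), against a median of 2.0%.

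Whether the origin difference itself differed between wild and lab fish was tested as an interaction, which was called at 11877 windows. By its estimate the difference was larger in wild fish at 7727 windows and in lab fish at 4150 windows. At 10653 windows the estimates had opposite signs in wild and lab fish, but neither was tested alone. Windows picked for a large interaction favour opposite signs, and 2250 of the 11877 were also called for origin. The single comparisons called 49 windows in opposite directions between wild and lab males, and 31 between wild and lab females. The region on NW_015098112.1 from 25801 to 30100 held 43 windows of 43 called for the interaction. Sulfidic wild females had 314 ± 89.7 CPM there and non-sulfidic wild females 81.9 ± 84.6 CPM. Sulfidic lab females had 254 ± 31.2 CPM and non-sulfidic lab females 287 ± 35.7 CPM (SD, n = 4 each). In wild males the groups overlapped there, with 289 ± 65.7 CPM in sulfidic (SD, n = 4) and 165 ± 112 CPM in non-sulfidic fish (SD, n = 3). The log2 difference was 1.19 ± 0.90 in wild males, with 10 of 43 windows called, and -0.40 ± 0.14 in lab males (SE). The region on NW_015096486.1 from 93001 to 97200 held 32 such windows of 42, with log2 differences of 1.21 ± 0.21 in wild males, 0.62 ± 0.23 in wild females, 0.00 ± 0.30 in lab males and -0.21 ± 0.20 in lab females (SE). Both regions were named by their calls in wild fish, which favours an interaction larger in wild fish. The test was edgeR at an adjusted p of 0.05, and its balance moved with the scaling: 7967 windows had a more positive difference in wild fish and 3910 a more negative one with TMM, 4474 and 4806 with library totals alone, and 2213 and 3291 with the trend against window level removed. Without the 3 lab libraries that lay apart on component 1 the interaction was called at 19343 windows, a test chosen after seeing the data. On every 20th window it was called at 721 windows, and without each fish in turn at 261 to 1249. It was 261 without sulfidic wild male 3 and 318 without non-sulfidic wild male 1. It was 345 and 385 without sulfidic lab males 3 and 4, 352 and 416 without sulfidic lab females 4 and 3, and 392 and 415 without non-sulfidic wild females 1 and 4. The count was 404 and 435 without sulfidic wild females 1 and 4, 405 without sulfidic wild male 1, 417 and 431 without non-sulfidic lab males 1 and 2, and 426 without non-sulfidic lab female 2. It rose to 1206 without sulfidic wild male 4 and 1249 without non-sulfidic lab male 4.

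Between wild and lab fish 969992 windows differed, 49.6% of those tested, with 480344 higher and 489648 lower in wild fish. The median log2 difference was 0.77 at the higher and -0.71 at the lower windows (edgeR, adjusted p of 0.05, n = 15 wild and 16 lab fish). A difference of at least 2-fold was present at 137040 higher and 109050 lower windows. Windows with a mean count from 20 to 40 were more often lower in wild fish (39.2% lower and 18.1% higher), and windows with a mean count from 5 to 6 more often higher (26.3% higher and 18.1% lower), as were windows with a mean count of at least 100 (32.1% higher and 12.2% lower). The labels give no batch, so rearing and any batch of collection or sequencing cannot be told apart. The same holds for origin and any batch that went with it, and for other differences between the springs.

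Male and female fish differed at 36 windows, 25 higher and 11 lower in males, in 19 regions (edgeR, adjusted p of 0.05). With a mean count of at least 10 the count was 7, and of 31 assignments of the sex labels on every 20th window 10 called at least as many as the real 3. These regions were picked out after their values were seen, since no naming rule covered them. On NW_015095052.1 from 26801 to 27100 females had 1.49 ± 0.520 CPM (SD, n = 16) and males 0.261 ± 0.217 CPM (SD, n = 15), with a smallest adjusted p of 1.1e-07 (edgeR). The sexes overlapped there: non-sulfidic wild female 2 had 0.265 CPM and sulfidic wild male 1 had 0.827 CPM. On NW_015099817.1 from 901 to 1100 males had 1.26 ± 0.873 CPM (SD, n = 15) and females 0.415 ± 0.811 CPM (SD, n = 16), with 1.51 ± 1.08 CPM in the 4 non-sulfidic wild females and at most 0.069 CPM on average in the other groups of females (smallest adjusted p = 2.1e-06, edgeR). Sulfidic lab male 4 had 0.035 CPM there, and non-sulfidic lab males 1 and 2 had 0.039 and 0.112 CPM. Non-sulfidic wild female 4 had 0 CPM, and the others of that group 1.455 to 2.35 CPM. The origin difference differed between the sexes at 7 windows, in 3 regions. The 4 windows on NW_015094819.1 from 304901 to 305300 had 0.147 ± 0.057 CPM in sulfidic lab females against 14.6 ± 3.89 CPM in non-sulfidic lab females, 10.7 ± 2.91 CPM in sulfidic lab males and 14.9 ± 5.26 CPM in non-sulfidic lab males (SD, n = 4 each; smallest adjusted p = 9.7e-07, edgeR). Sulfidic wild female 3 had 0.229 CPM there and the other 3 sulfidic wild females 4.66 to 7.77 CPM. Without the 3 lab libraries that lay apart, 14 windows were called for the difference between the sexes in the origin effect and 19 windows between the sexes.

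**Figure D5:**
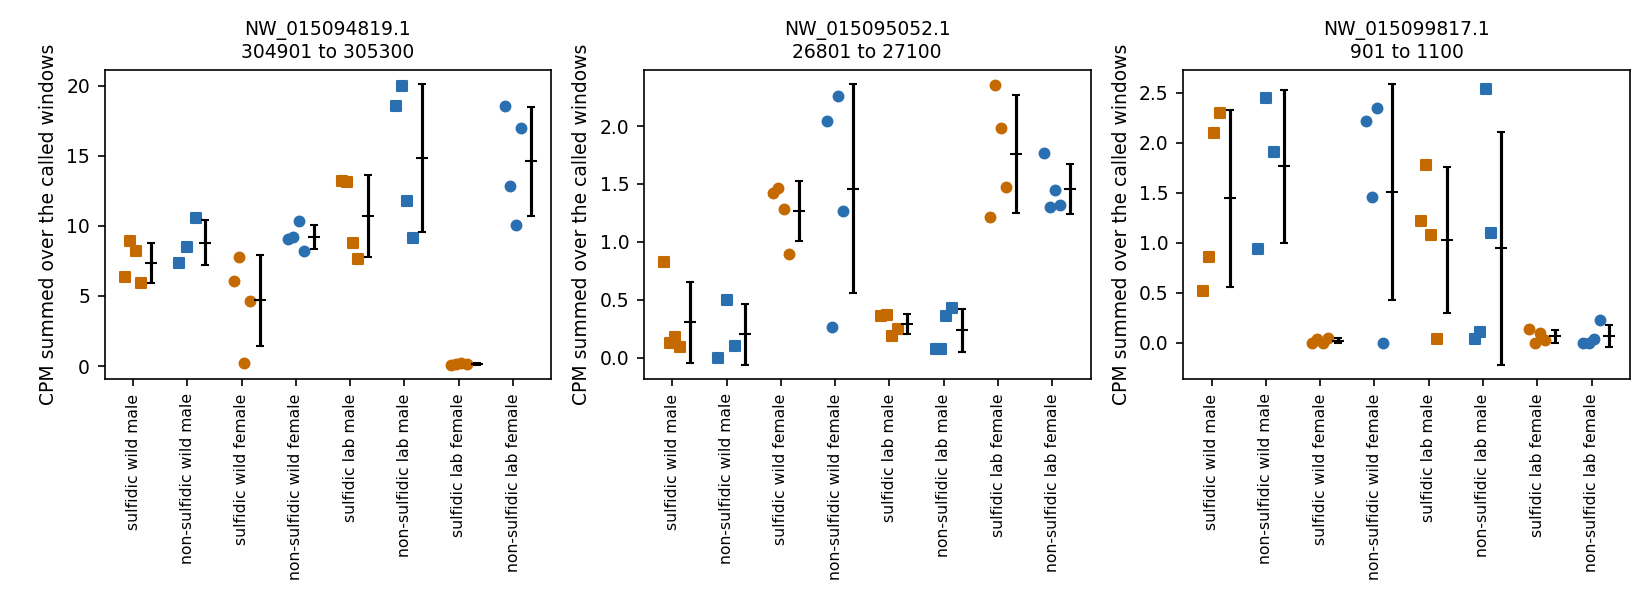
Signal of each fish in CPM summed over the called windows (y axis) in 3 regions that differed by sex, or in the origin effect between the sexes, for the 8 groups (x axis); squares are males, circles females, bars the mean and SD. On NW_015094819.1 the 4 sulfidic lab females have 0.147 ± 0.057 CPM, and on NW_015095052.1 females have 1.49 ± 0.520 CPM against 0.261 ± 0.217 CPM in males.

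The authors' tables list 11263 higher and 7118 lower windows in wild males at their adjusted p of 0.05, 10657 and 6240 in wild females, 8185 and 9167 in lab males, and 4901 and 12649 in lab females. Of the windows called here, 73.0% in wild males, 68.9% in wild females, 91.9% in lab males and 84.5% in lab females were also called there in the same direction, and 0 in the opposite direction.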

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

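Removing the trend against window level was chosen after seeing the data. Its tests in wild males, the tests of single lab libraries and the exchange of residuals for the interaction were chosen after their results were seen, while the other splits of the fish were planned.

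The origin difference itself differed between wild and lab fish at 11877 windows (edgeR, adjusted p of 0.05), 7967 with a more positive and 3910 with a more negative difference in wild fish. A candidate explanation is that libraries differ in how enrichment follows the level of a window. With that trend removed 46.3% as many windows were called for this contrast, 4279 of them also called before, so for part of these windows the trend cannot be told apart from a difference between the fish. For the difference between wild and lab fish 98.9% as many windows were called without the trend, which argues against it as the whole cause there, as it does for windows lower in sulfidic wild males, 82.6% of which were called in both; of the higher windows 45.4% (4646 of 10224) were, so for these the trend cannot be told apart from a difference between the fish. A batch that went with rearing, and changes in the lab stock over the generations bred there, both stay open and were not tested.

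For this interaction, residuals of a fit without it were exchanged between fish of the same rearing and sex, on every 20th window. This keeps the fitted origin and rearing effects, but not the number of origin calls. The exchanged data called 4703 to 16059 windows for the origin effect, against 2593 in the real data. Of 31 assignments only the real 1 called as many as 721 windows for the interaction, and the highest other called 2. That is the smallest share 31 assignments can give, so it argues against chance but cannot exclude it. Exchanging the origin labels or the rearing labels, which removes that effect as well, gave at most 2 and 0 windows in the other assignments. With rearing labels exchanged, 1 of 31 assignments called as many windows between wild and lab fish as the real one, 48224 against 8124 in the highest other. With origin labels exchanged it was 1 of 31 for the origin effect, with 2593 against 3. Both argue against chance, at the smallest share that 31 assignments allow and without adjustment over the contrasts. In the single comparisons 1 of 35 splits called as many windows as the real one. There were 835 against 34 in the highest other split in wild females, 514 against 7 in lab males and 434 against 32 in lab females. These argue against chance, at the smallest share that 35 splits allow. In wild males the real split called 791 windows, again 1 of 35, but the split that sets sulfidic wild male 4 and the 3 non-sulfidic wild males against the other sulfidic wild males called 753; it differs from the real split in the side of 1 fish. For the sex difference 10 of 31 assignments called at least the real 3 windows, with up to 11 in another, so chance cannot be excluded for that count. For the origin difference between the sexes, called at 7 windows, the subset held 0 of them in edgeR and 0 in DESeq2 (5500 and 3628 windows at an unadjusted p of 0.05), so 31 of 31 assignments called at least as many, with up to 6 in another, and this test says nothing on chance.

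Non-sulfidic lab female 3 lay at 0.467 between the origins, where the other non-sulfidic lab females lay from 0.007 to 0.073. A fish of sulfidic origin under a wrong label is argued against by that position, since sulfidic lab females lay from 0.932 to 1.02. DNA of a sulfidic fish mixed into the library is a candidate explanation that stays open. The share of sulfidic signal was 0.209 higher at windows higher in sulfidic fish than at windows lower in them. That was above the other non-sulfidic lab females (-0.077 to 0.149) and 12 mixtures made from these libraries (-0.071 to 0.101). Over 110 scaffolds the interquartile range of the share was 0.512, against 0.218 to 0.340 in the mixtures and 0.299 to 0.425 in the other non-sulfidic lab females. A spread above the mixtures was thus not particular to this fish, and the fish mixed in need not be one of those used. A fish with ancestors of both origins was not tested. Non-sulfidic lab male 4, near the wild fish on component 1, had a mean count of 5.55 at 324 windows read in wild but almost not in other lab fish of its origin, and 4.27 at 14 windows with the reverse pattern; at windows chosen without them, wild fish of its origin had 6.80 to 7.41 and 0.65 to 1.82, and the other lab fish 0.54 to 2.15 and 5.43 to 10.59, which argues against a wild fish of that spring under a lab label.

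Chance alone marks about 1 in 20 groups as holding a fish far from the others. Here 2 of 49 groups were marked for measures of whole libraries and 10 of 112 for named regions and windows, which share fish and neighbouring windows. Non-sulfidic wild female 3 had 5 or more counts at 24.4% of windows, and the other 3 fish of its group at 30.7% to 31.4%. This share is not scaled to depth, and its window counts summed to 29621412 against 37442972 to 39947183 in the others. At the window on NW_015098560.1 from base 30801 non-sulfidic lab male 4 had 4.83 CPM and the others of its group 0.619 to 0.964 CPM. At the window on NW_015097309.1 from 56101 sulfidic wild male 3 had 0.223 CPM against 0.887 to 0.952 CPM. At the adjacent window from 56201 non-sulfidic wild female 4 had 0.036 CPM (1 count) and non-sulfidic lab female 3 had 0.071 CPM (2 counts), while the others of their groups had 0. Sulfidic wild female 2 had 0.038 CPM (1 count) at the window on NW_015099381.1 from 8901. Sulfidic wild male 2 had 0.031 CPM (1 count) at that on NW_015094692.1 from 196101, where the others of their groups had 0. Any count marks a group that is otherwise at 0, so the rate of 1 in 20 does not hold for these. On NW_015098779.1 from 22101 to 24900 sulfidic wild male 2 had 13.6 CPM against 2.64 to 3.18 CPM. On NW_015096559.1 from 91701 to 98800 non-sulfidic wild female 2 had 190 CPM against 17.4 to 31.1 CPM. On NW_015094562.1 from 155601 to 161500 sulfidic lab male 3 had 13.9 CPM against 31.3 to 31.6 CPM, and from 156001 to 161500 non-sulfidic lab female 3 had 18.8 CPM against 6.84 to 8.82 CPM.

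Single items also differed in their origin difference between wild and lab fish (edgeR interaction at an adjusted p of 0.05). At the window on NW_015098560.1 from 30801 the log2 difference was larger in wild fish by 3.05 (adjusted p = 7.4e-05). The region on NW_015098112.1 from 25801 to 30100 held 43 such windows of 43, and that on NW_015096486.1 from 93001 to 97200 held 32 of 42. The region on NW_015097842.1 from 18901 to 23200 held 8 of 43, that on NW_015094562.1 held 3 of 59 from 155601 to 161500 and 3 of 55 from 156001 to 161500, and that on NW_015096896.1 from 86401 to 91100 held 1 of 47. In the regions named in wild fish the difference was larger in wild fish at all of these windows. On NW_015094562.1 and NW_015096896.1, named in lab fish, it was larger in wild fish at 0 of them. Regions were named by calls in these same fish, which favours an interaction toward the comparison that named them.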

How the results depend on the processing

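Removing the trend against window level, leaving out windows with a count above 150, leaving out the libraries that lay apart, and all alternatives of named regions and windows were chosen after seeing the data. Named items were picked by their calls in these same fish, and regions were weighed only in the comparison that named them. Their signs were therefore close to fixed in advance. Of 560 alternatives of named regions and windows, under library totals and without each fish in turn, 0 had the opposite sign. The fold moved by at most 1.5 times in 541. The other 19 left out 1 fish. In wild males, NW_015095180.1 from 224501 moved from 1.61 to 2.28 and from 224601 from 1.47 to 2.06 without non-sulfidic wild male 2, and NW_015097309.1 from 56201 moved from 2.64 to 3.29 without sulfidic wild male 3. NW_015097917.1 from 20301 moved from 2.72 to 3.63 and 2.03 without non-sulfidic wild males 2 and 3, and NW_015098779.1 from 22101 from -2.96 to -3.68 and -2.33 without non-sulfidic wild males 1 and 2. In wild females the farthest moved was NW_015097420.1, from 2.66 to 1.14 without non-sulfidic wild female 3. In lab males it was NW_015097917.1, from 1.91 to 3.57 without sulfidic lab male 4. With the trend removed 43.2% of called windows were higher in wild males (66.7% before), 40.4% in wild females (53.6% before), and 51.5% in lab females (42.6% before). With a mean count of at least 10, the windows called numbered 7484 in wild males, 8793 in wild females, 6016 in lab males, 6011 in lab females, 33521 for origin, 6001 for the origin difference between wild and lab fish, 4 for that between the sexes, 499337 between wild and lab fish and 7 between the sexes, since fewer windows were tested. At an adjusted p of 0.01 the 4 comparisons had 5546, 7590, 4709 and 4398 windows, by construction. In 1000-base bins wild males had 6257, wild females 7242 and lab males 6172 called bins, while lab females had 9155 bins against 9150 windows; the cause was not tested. Regions of at least 2 windows numbered 3236, 3044, 2110 and 1883. On every 20th window DESeq2 called 265 windows in wild males, 170 in wild females, 235 in lab males and 178 in lab females, where edgeR called 791, 835, 514 and 434. DESeq2 gave no adjusted p for 96957 of 102061 windows in wild males and 20539 of 96294 in lab females, so these 2 counts are not like for like, but for 10 in wild females and 7 in lab males only. It called 0 windows between the sexes (2153 at an unadjusted p of 0.05), where edgeR called 3 (3649). On every 20th window edgeR without a count minimum called 711 windows in lab females, against 434 with it. The cause was not tested. Without the 3 libraries that lay apart the origin difference between wild and lab fish was called at 19343 windows, that between the sexes at 14 and the sex difference at 19, and with the trend removed the first was called at 5504; the cause was not tested. Sharing between comparisons counted as regions overlapping by 1 base was 28% for wild males and wild females, 15.6% for wild males and lab males, 16.8% for wild males and lab females, 21.2% for wild females and lab males, 22.8% for wild females and lab females and 34.1% for lab males and lab females. By at least 50% of the shorter region it was 27.9%, 15.5%, 16.6%, 21%, 22.5% and 34.0%; the cause was not tested. The sign share from wild to lab males was 79.4% at an adjusted p of 0.01 and 77.5% with the trend removed (exact p = 0.0286 each), and that in females was 82.2% and 81.1% (exact p = 0.0286 and 0.0143), but 68.6% with 1 window per region (exact p = 0.0714). Over the 10% of windows with the highest variance origin held 95.3% of component 2 and 0.1% of component 3, against 35.9% and 56.2% over all windows. Its share there lay in component 2 and was not lost. The cause was not tested in any of these settings.

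Without each fish in turn the windows called ranged from 6495 to 25886 in wild males (6495 and 7083 without non-sulfidic wild males 1 and 2, 7762, 8913 and 25886 without sulfidic wild males 1, 3 and 4), 5642 to 12635 in lab males (5914 and 5642 without sulfidic lab males 1 and 4) and 5157 to 11837 in lab females (6076 without non-sulfidic lab female 1 and 5157 without sulfidic lab female 4), and the sign share from wild to lab females from 71.6% to 75.6%, with fewer fish and 35 splits. On every 20th window the origin difference between wild and lab fish ranged from 261 to 1249 around 721, lowest without sulfidic wild male 3 and highest without non-sulfidic lab male 4. The sex difference ranged from 0 to 5 around 3: 0 without sulfidic lab female 2 or 4, sulfidic lab male 1 or 2, sulfidic wild female 2, 3 or 4, or sulfidic wild male 4, 1 without non-sulfidic lab female 3, sulfidic lab female 1 or sulfidic wild male 3, and 5 without non-sulfidic lab female 4, non-sulfidic lab male 1 or 4, non-sulfidic wild male 1 or sulfidic lab male 4. Depth limits windows under a mean count of 5, which were not tested. Of 2-fold changes in single comparisons 24% to 32% were recovered in simulated data, whose spread between fish was fixed and not measured. Tests of genes called and of gene lists, with their alternatives, were not run, since no annotation was used here.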

Other observations

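The tests of sequence missing from fish of either origin, and the regions described here, were chosen after the result was seen.

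Regions on different scaffolds had much the same levels in the same groups. On NW_015095229.1 from 183401 to 189400 the level was 39.1 ± 5.75 CPM in sulfidic wild males, 49.9 ± 2.81 CPM in sulfidic wild females, 34.7 ± 9.51 CPM in sulfidic lab males and 27.3 ± 9.57 CPM in sulfidic lab females (SD, n = 4 each). On NW_015097072.1 from 32801 to 38000 the same groups had 35.6 ± 6.88, 45.5 ± 3.53, 32.7 ± 7.07 and 25.3 ± 6.41 CPM (SD, n = 4 each). In non-sulfidic fish the levels were 87.2 ± 8.63 CPM on the former and 79.8 ± 4.96 CPM on the latter in wild males (SD, n = 3), and 70 ± 18.5 and 65.6 ± 16 CPM in lab females (SD, n = 4). On scaffolds NW_015097158.1 and NW_015097159.1, at the same coordinates from 18301 to 18500, sulfidic wild females and sulfidic lab females had 0 CPM. Non-sulfidic wild females had 1.22 ± 0.334 and 0.969 ± 0.245 CPM, and non-sulfidic lab females 1.16 ± 0.804 and 0.836 ± 0.687 CPM. Sulfidic wild males had 0.422 ± 0.594 and 0.284 ± 0.347 CPM, and sulfidic lab males 0.821 ± 0.580 and 0.830 ± 0.601 CPM. Non-sulfidic lab males had 1.71 ± 0.326 and 1.34 ± 0.558 CPM (SD, n = 4 each).

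Some regions were on average nearly empty in 1 group of sulfidic fish. On NW_015098493.1 from 12001 to 16500 sulfidic lab males had 0.651 ± 0.293 CPM, sulfidic lab females 19.7 ± 19.3 CPM, sulfidic wild males 6.43 ± 6.52 CPM and sulfidic wild females 16.3 ± 4.39 CPM (SD, n = 4 each). The SD of log2 CPM was 2.72 in these lab females and 2.19 in the wild males, so single fish of these groups could be nearly empty too. On NW_015094819.1 from 343401 to 343600, on the same scaffold as the region nearly empty in sulfidic lab females, these females had 0.017 ± 0.020 CPM and non-sulfidic lab females 1.04 ± 0.370 CPM. Sulfidic lab males had 0.728 ± 0.216 CPM, sulfidic wild males 0.535 ± 0.217 CPM and sulfidic wild females 0.222 ± 0.117 CPM (SD, n = 4 each).

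The windows called in all 4 comparisons may differ in sequence between the springs and not in methylation. Of the 275 higher windows 0.36% had at most 3 counts over all 15 non-sulfidic fish. For most of them this argues against sequence missing from all 15 fish. The sum includes non-sulfidic lab female 3, which lay at 0.581 between the origins at windows higher in sulfidic fish. Sequence missing from the other non-sulfidic fish therefore stays open. Of the 513 lower windows 10.14% had at most 3 counts over all 16 sulfidic fish, so sequence missing from sulfidic fish stays open for a part of them; the median over the lower windows was 74 counts summed over the sulfidic fish. Repeats that reach the highest counts stay open for a part as well, since 88.3% of the windows had every count at or under 150. The share was 81.8% of the higher and 91.8% of the lower windows, and that over all tested windows is not given here. High counts were rare among the 1956264 windows tested in all fish, of which 6744 had a mean count of at least 100. Differences in copy number, and sequence variants in the scaffolds, cannot be weighed with these tables, and a difference in methylation between the springs was not tested apart from them.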
